A study of Homo sapiens with 9 samples.

How the data were processed

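RNA was measured by sequencing in 9 libraries of 22Rv1 cells, 3 with a hairpin against GFP and 3 with each of 2 hairpins against CHD9. Per the labels' protocols, the cells were grown in RPMI medium with serum, RNA was prepared with a column kit, and libraries were made from polyadenylated RNA with a directional kit. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR to hg38, and DESeq2 was used. The versions, the read counter, its strand setting and the annotation release are not given in the sources used here. The values deposited by the authors are counts, whole numbers of reads per gene with no normalisation, in a single table of all 9 libraries, and replicates were not pooled. Because the strand setting is not given, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as HLA and histone genes or ribosomal protein genes with processed pseudogenes, are uncertain where reads map to more than 1 place.

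The table has 67071 gene identifiers. A table of gene names holds 60370 of them and the GENCODE 29 annotation 58496, and together these gave a symbol for 60659. No line of the table lacked a gene, so all counts entered the library totals. Coordinates are those of GENCODE 29 on GRCh38, the build that hg38 names. Every sample was assigned to its group and replicate number by its title, and each column to its sample by its name.

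The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10, which left 16855 genes. Libraries were scaled by TMM, and CPM are computed on the scaled library totals. A quasi-likelihood model with a mean for each of the 3 groups was fitted to all 9 libraries in edgeR (R 4.3.3), and 4 contrasts were tested: the mean of both CHD9 hairpins against shGFP, each hairpin against shGFP, and hairpin 1 against hairpin 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Intervals on the CPM of a single library are exact Poisson intervals at 95% and cover counting error only. Counts of genes called with both hairpins were set beside 20 simulations of unchanged hairpin groups against the same controls, and beside the product of the 2 numbers of calls over the number of genes tested.

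Each of 36 lists was tested with camera in limma 3.58.1 on log2 CPM with voom weights, with the preset inter-gene correlation of 0.01 and again with a correlation estimated for each list, if at least 5 of its genes were tested. Benjamini-Hochberg adjustment was over the 34 lists that were. The directional test fry was run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. Counts of members called are given after adjustment over all genes tested and adjusted over the list alone.

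Named genes are CHD9 and the other CHD genes. They also include the 10 genes with the highest and the 10 with the lowest mean log2 fold change among genes of at least 5 CPM called in the same direction in the mean contrast and with each hairpin, and up to 4 members of each list with the smallest p in the mean contrast. The 5 genes with the highest and the 5 with the lowest log2 difference between the hairpins, at 5 CPM or more, complete the rule. Symbols that are clone names, pseudogene names or bare identifiers were passed over in the ranked parts. Further members are named to describe a list. The rule gives 163 genes, and some of them are not reported here.

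The gene test was tried on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed among 16617 tested. For the mean of both hairpins, 62.7% of genes changed 1.25-fold, 73.8% of those changed 1.5-fold and 86.2% of those changed 2-fold were called, among changed genes that passed the filter, and 11 of 157 calls were unchanged genes. For hairpin 1 the shares were 58.2%, 67.7% and 83.1%, with 10 of 147 calls unchanged, and for hairpin 2 they were 59.7%, 73.8% and 76.9%, with 10 of 148. Between the hairpins, where the simulated changes were identical, 1 gene was called. In the simulation camera called 0 of 23 lists without a changed gene, at an adjusted p under 0.05. It called 20 of 20 random lists of 20 genes moved by 1.25-fold, each tested alone at an unadjusted p under 0.05. Simulated genes varied independently, so these counts cannot tell how often camera calls unchanged lists whose genes vary together.

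The alternatives tried were size factors of DESeq2 in edgeR, the DESeq2 1.42.0 Wald test, voom with limma, no low-count filter, a filter of at least 1 CPM in 6 libraries, an adjusted p under 0.01, a minimum fold change of 1.5 in glmTreat, fits on the compared groups alone or with the 6 CHD9 libraries as a single group, the replicate number as a block, and leaving out each library in turn. A correction for GC content and exonic length, the length of all annotated exons of a gene joined, was added after the data were seen. It fits a smooth curve of each library's log2 CPM, relative to the mean of all libraries, on both properties with mgcv 1.9.3 and uses the fitted values as offsets. Alternatives planned for values other than counts do not apply.

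To look for hairpin seed matches, the longest annotated 3' UTR, of at least 50 bases, was taken from the GENCODE 29 transcript sequences for 12970 tested genes. Fold changes were regressed on UTR length, UTR GC content and expression. Words of 7 bases carried by at least 100 genes were then scored by how far the residuals of carriers lay from those of other genes, against 100 permutations. Planted words with a shift of 0.1 on the log2 scale were found in 10 of 10 tests on permuted residuals. Only words carried by many more genes than that minimum were planted, so the tests do not cover rarer words. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for sequences and plots. Samples were grouped as the labels give them and none was left out.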

Results

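RNA was sequenced from 22Rv1, a human prostate carcinoma cell line that was established from a xenograft and expresses the androgen receptor. The 9 libraries form 3 groups of 3. Control cells carried a short hairpin RNA against GFP (shGFP), and the knockdown cells carried either of 2 hairpins against CHD9, called hairpin 1 (shCHD9_1) and hairpin 2 (shCHD9_2) here. CHD9 is a chromodomain helicase of the ATP-dependent chromatin remodellers. The series is about editing RNA methylation with METTL3, and its design text names a single comparison, control knockdown against CHD9 knockdown. Total counts were 18911142, 22544162 and 26103588 in shGFP, 20572689, 22878947 and 27275052 with hairpin 1, and 25126026, 31968602 and 20884244 with hairpin 2. Between 15896 and 17375 genes reached 10 counts in a library, and 16855 genes were tested. The 10 most abundant genes took 5.19% to 5.64% of the counts of a library, and mitochondrial transcripts took 3.66% to 4.07%.

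Libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 1.72 to 2.86 over the 9 pairs within groups, and each was treated as a replicate. Pairs from different groups gave 9.68 to 30.5. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The common coefficient of variation between replicates was 2.74%. On the first principal component of the log2 CPM, 42.9% of the variance, shGFP libraries lay between -34.5 and -30.7, hairpin 1 libraries between 24.2 and 26.3, and hairpin 2 libraries between 6.37 and 7.78.

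CHD9 mRNA (ENSG00000177200.17, chromosome 16, 53055033 to 53329150, plus strand, GRCh38) was lower in each of the 6 knockdown libraries than in each of the 3 shGFP libraries, a separation that chance gives, in either direction, for 2.38% of genes. The shGFP libraries had 433, 466 and 607 CHD9 counts, or 22.8, 20.6 and 23.2 CPM, a mean of 22.2 ± 1.42 CPM (SD, n = 3). With hairpin 1 there were 298, 375 and 399 counts, or 14.8, 16.7 and 14.9 CPM, a mean of 15.4 ± 1.07 CPM (SD, n = 3). With hairpin 2 there were 463, 610 and 409 counts, or 18.4, 18.8 and 19.3 CPM, a mean of 18.8 ± 0.465 CPM (SD, n = 3). CHD9 fell to 0.695 of the shGFP level with hairpin 1 (log2 fold change -0.52, SE 0.07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.1e-08). It fell to 0.847 of that level with hairpin 2 (log2 fold change -0.24, SE 0.07, adjusted p = 0.0060 by the same edgeR test). The hairpin 2 call was lost without shGFP replicate 3 (log2 fold change -0.20, edgeR Benjamini-Hochberg adjusted p = 0.054), while the other alternatives gave an adjusted p of 0.0028 to 0.027. The fall was larger with hairpin 1 than with hairpin 2 by -0.28 on the log2 scale (edgeR Benjamini-Hochberg adjusted p = 0.0024). Averaged over both hairpins, CHD9 fell by 0.38 on the log2 scale (SE 0.06).

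**Figure D1:**
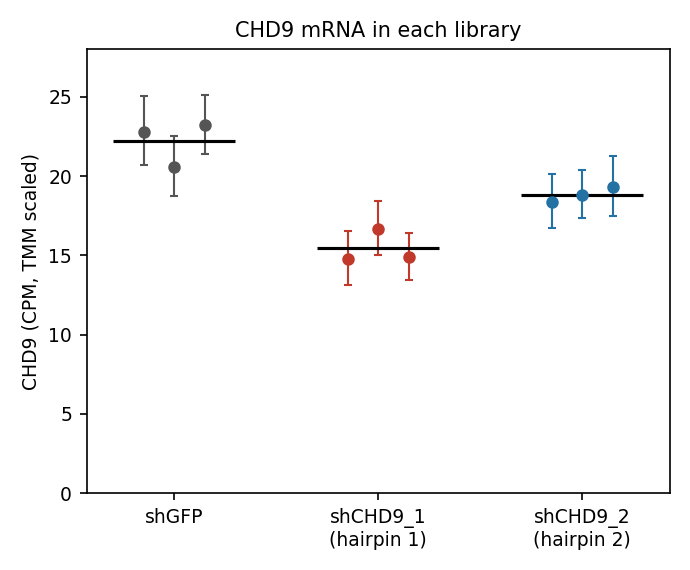
CHD9 in CPM (vertical axis, TMM scaled) in each of the 9 libraries, grouped as shGFP, shCHD9_1 and shCHD9_2 on the horizontal axis; points are libraries, error bars are exact Poisson 95% intervals that cover counting error only, and black lines are group means. The group means were 22.2, 15.4 and 18.8 CPM.

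The comparison named by the series, CHD9 knockdown against control knockdown, was made first as the mean of both hairpins against shGFP. Chaperones of the endoplasmic reticulum, enzymes of cholesterol synthesis, and genes of DNA replication, p53 and the interferon response fell as groups. Androgen receptor targets and Notch pathway genes rose as groups. The largest falls with both hairpins included AGR2 (ENSG00000106541.12, chromosome 7, 16791811 to 16833433), a protein disulfide isomerase, from 50.4 ± 0.668 CPM in shGFP to 4.53 ± 0.344 with hairpin 1 and 9.38 ± 0.540 with hairpin 2 (SD, n = 3 each). The largest rises included TRIB2 (ENSG00000071575.11, chromosome 2, 12716889 to 12742734), a pseudokinase gene, from 5.72 ± 0.453 to 34.2 ± 1.15 and 21.2 ± 0.202 CPM (SD, n = 3 each).

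At an adjusted p under 0.05, 7675 of the 16855 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 3767 of them higher and 3908 lower. Most changes were small. The median size of a called log2 fold change was 0.27, 1366 called genes changed by more than 1.5-fold, and 490 by more than 2-fold, 252 higher and 238 lower.

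Among genes of at least 5 CPM called the same way with each hairpin, the 10 with the largest mean fall were led by AGR2 (log2 fold change -2.96, SE 0.06), A2M, a protease inhibitor of the plasma (-2.80, SE 0.12), and TRGC1, of the T cell receptor gamma locus (-2.60, SE 0.07). ALB, which encodes albumin, fell from 661 ± 10.9 CPM in shGFP to 123 ± 5.61 with hairpin 1 and 179 ± 1.54 with hairpin 2 (SD, n = 3 each). DHRS2, a short-chain dehydrogenase, fell by 2.06 on the log2 scale, and the proteoglycans SPOCK2 and VCAN fell by 2.05 and 1.80. FLRT3, TMEM45A and the calcium-binding protein gene S100P fell by 1.80, 1.71 and 1.69. The 10 with the largest mean rise were led by CYP4F22, a cytochrome P450 (log2 fold change 2.56, SE 0.11), TRIB2 (2.24, SE 0.07) and CYP1A2, another cytochrome P450 (2.11, SE 0.11). STMN3, a stathmin, rose from 17.2 ± 1.74 CPM to 105 ± 0.624 with hairpin 1 and 42.3 ± 2.63 with hairpin 2 (SD, n = 3 each). CAMKV rose by 1.73 on the log2 scale, OAF by 1.56, the protein kinase C gene PRKCA by 1.52, the inhibin subunit gene INHBB by 1.47 and the synaptic scaffold gene SHANK1 by 1.43. The edgeR Benjamini-Hochberg adjusted p of the 20 genes was 6.3e-13 (SHANK1) or smaller. For each of the 20 genes all 6 knockdown libraries lay beyond all 3 shGFP libraries, a separation that chance gives for 2.38% of genes and that the choice of these genes makes likely.

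Within the CHD family, 5 of 10 genes passed the test, and the list as a whole did not (camera, Benjamini-Hochberg adjusted p = 0.88). CHD1, a paralogue of CHD9, fell by 0.50 on the log2 scale (SE 0.04), from 64.1 to 41.7 CPM with hairpin 1 and 49.2 CPM with hairpin 2. CHD5 rose by 0.34 (SE 0.07). CHD3 and CHD7 had log2 fold changes of 0.08 and 0.10 that passed the test. Both calls were lost after a correction for GC content and exonic length (log2 fold changes -0.03 and 0.03). They were also lost without shGFP replicate 3 (0.06 and 0.07). The log2 fold changes of CHD2 (0.03), CHD4 (0.10), CHD6 (0.07), CHD8 (-0.04) and CHD1L (0.21) did not pass, although CHD8 passed after that correction (-0.15) and CHD6 without replicate 1 of either CHD9 hairpin (0.09). Adjusted over the list alone, the counts were the same, 3 higher and 2 lower.

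Of 34 gene lists with at least 5 tested genes, 15 passed the test on the mean of both hairpins, 9 lower and 6 higher (camera, Benjamini-Hochberg adjusted p under 0.05), and 7 of these also passed with an inter-gene correlation estimated from the data. The unfolded protein response list, made up of chaperones and quality-control genes of the endoplasmic reticulum, had 17 of 19 members lower, none higher and 2 not passed, with the same counts adjusted over the list alone (camera, adjusted p = 1.1e-16, and adjusted p = 0.0059 with an estimated correlation). HSP90B1 fell from 2285 ± 61.7 CPM to 1217 ± 9.64 with hairpin 1 and 1793 ± 10.7 with hairpin 2 (SD, n = 3 each). HSPA5, the chaperone BiP, fell by 0.61 on the log2 scale, PDIA4 by 0.62 and CALR, calreticulin, by 0.41, each with an SE of 0.02. CANX (-0.03) and ERN1 (0.04), the sensor IRE1, did not pass.

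Cholesterol synthesis genes had 21 of 25 members lower, 1 higher and 3 not passed, the same adjusted over the list alone (camera, adjusted p = 2.1e-11, and adjusted p = 0.0059 with an estimated correlation). HMGCS1, which makes HMG-CoA, fell by 0.67 on the log2 scale (SE 0.03). STARD4, a sterol transporter that carries CTTCTAA in its annotated 3' UTR, fell by 1.34. FDPS was the member that rose (0.10).

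DNA repair genes had 23 of 33 members lower, 3 higher and 7 not passed (24 and 4 adjusted over the list alone). The camera adjusted p was 1.7e-05, and adjusted p = 0.082 with an estimated correlation. The checkpoint scaffold TOPBP1 fell by 0.43 on the log2 scale and the end-joining gene XRCC4 by 0.63, while PRKDC, the DNA-dependent protein kinase, rose by 0.31, as did CHEK2 (0.14) and XRCC2 (0.11). DNA replication genes had 19 of 36 members lower, 2 higher and 15 not passed (20 and 2 adjusted over the list alone), with a camera adjusted p of 0.00017, and adjusted p = 0.042 with an estimated correlation. The ribonucleotide reductase subunit gene RRM2 fell by 0.45 (SE 0.02), CCNE2, cyclin E2, by 0.53, MCM10 by 0.37 and CDC6 by 0.32, while MCM4 (0.08) and UHRF1 (0.07) rose. Mitosis genes had 23 of 40 members lower, 6 higher and 11 not passed, the same adjusted over the list alone (camera, adjusted p = 0.00051). The mitosis call was lost with an estimated correlation (adjusted p = 0.096) and after the GC content and length correction (camera, adjusted p = 0.11). CENPE, a kinetochore motor, fell by 0.93 (SE 0.04), and HMMR, a spindle protein gene, by 0.69 (SE 0.03). ANLN, a cytokinesis scaffold, rose by 0.61 (SE 0.03), and the proliferation marker MKI67, the kinases AURKA and PLK1, and the kinesins KIF20A and KIF11 rose by 0.08 to 0.24. Replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail while the libraries were made from polyA RNA, had 6 of 11 members lower, none higher and 5 not passed, the same adjusted over the list alone (camera, adjusted p = 0.015, and adjusted p = 0.096 with an estimated correlation). H1-2 fell by 1.31 on the log2 scale (SE 0.09) and H2BC12 by 0.90 (SE 0.09).

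Targets of p53 had 14 of 25 members lower, 2 higher and 9 not passed (16 and 2 adjusted over the list alone), with a camera adjusted p of 0.00056, and adjusted p = 0.042 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, fell from 310 ± 5.06 CPM to 189 ± 6.28 with hairpin 1 and 155 ± 9.20 with hairpin 2 (SD, n = 3 each). The stress cytokine GDF15 fell by 0.71 on the log2 scale and PHLDA3 by 0.58, while BBC3, the pro-apoptotic gene PUMA, rose by 0.38 and TP53INP1 by 0.15. MDM2, a classical p53 target, had a log2 fold change of 0.04 and did not pass. Interferon response genes had 16 of 30 members lower, 2 higher and 12 not passed, the same adjusted over the list alone (camera, adjusted p = 0.0024, and adjusted p = 0.043 with an estimated correlation). STAT2, a transducer of interferon signals, fell by 0.50 on the log2 scale (SE 0.05) and LGALS3BP by 0.56. The class I antigen genes HLA-B and HLA-C, whose counts are uncertain because reads can map to more than 1 HLA gene, fell by 0.83 and 0.62. B2M, which encodes the class I light chain, rose by 0.24 and ISG15 by 0.08. Immediate early genes had 14 of 25 members lower, 3 higher and 8 not passed (14 and 4 adjusted over the list alone), with a camera adjusted p of 0.011, and adjusted p = 0.12 with an estimated correlation. The ERK feedback inhibitor SPRY4 fell by 1.14 on the log2 scale (SE 0.05), IER5 by 0.49 and EGR1 by 0.45, whereas MYC rose by 0.32, JUNB by 0.11 and FOSL1, at 1.05 CPM, by 0.93.

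Androgen receptor targets had 13 of 22 members higher, 4 lower and 5 not passed, the same adjusted over the list alone (camera, adjusted p = 0.00021, and adjusted p = 0.042 with an estimated correlation). The kallikrein KLK4 rose from 189 ± 2.68 CPM to 362 ± 2.52 with hairpin 1 and 383 ± 13.8 with hairpin 2 (SD, n = 3 each). NDRG1, which also responds to hypoxia, rose by 1.21 on the log2 scale (SE 0.04), KLK2 by 0.55 and KLK3, which encodes prostate-specific antigen, by 0.50. ELL2, an elongation factor gene, fell by 0.45, SLC45A3 by 0.31, TMEM79 by 0.16, and STEAP4, at a mean of 0.324 CPM, had a log2 fold change of -2.12. Notch pathway genes had 9 of 12 members higher, none lower and 3 not passed, the same adjusted over the list alone (camera, adjusted p = 0.00019, and adjusted p = 0.042 with an estimated correlation). The members that rose included the ligand JAG2 (0.41 on the log2 scale, SE 0.04), the receptor NOTCH3 (0.32, SE 0.03), the glycosyltransferase LFNG (0.66, SE 0.08) and HES6 (0.48, SE 0.06). The classical targets HES1 (0.06) and HEY1 (0.24) did not pass.

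Ribosomal protein genes had 28 of 37 members higher, none lower and 9 not passed, the same adjusted over the list alone (camera, adjusted p = 1.1e-09, and adjusted p = 0.31 with an estimated correlation). RPL22 rose by 0.41 on the log2 scale (SE 0.03), RPL30 by 0.21 and RPL3 by 0.17, and RPL8 by 0.15, a call that was lost after the GC content and length correction. Mitochondrially encoded transcripts had 8 of 15 members higher, 1 lower and 6 not passed, the same adjusted over the list alone (camera, adjusted p = 0.00021, and adjusted p = 0.31 with an estimated correlation). The ribosomal RNAs MT-RNR2 and MT-RNR1 rose by 0.64 and 0.41 and MT-ND5 by 0.17, while MT-CO1 fell by 0.05. The ATF4 and amino acid response list had 15 of 28 members higher, 7 lower and 6 not passed (16 and 7 adjusted over the list alone), with a camera adjusted p of 0.012, and adjusted p = 0.17 with an estimated correlation. The amino acid transporter subunits SLC7A5 and SLC3A2 rose by 0.86 and 0.71, each with an SE of 0.02, and MTHFD2, of the mitochondrial folate pathway, by 0.37. The transporter gene SLC38A2 fell by 0.65, and CTH, DDIT3, ATF3, PSAT1, AARS1 and GARS1 fell by 0.11 to 0.43. Genes of small RNA silencing had 7 of 13 members higher, none lower and 6 not passed, the same adjusted over the list alone (camera, adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). The Argonaute genes AGO1 and AGO4 rose by 0.53 and 0.33, and TNRC6B, of the silencing complex, by 0.23.

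**Figure D2:**
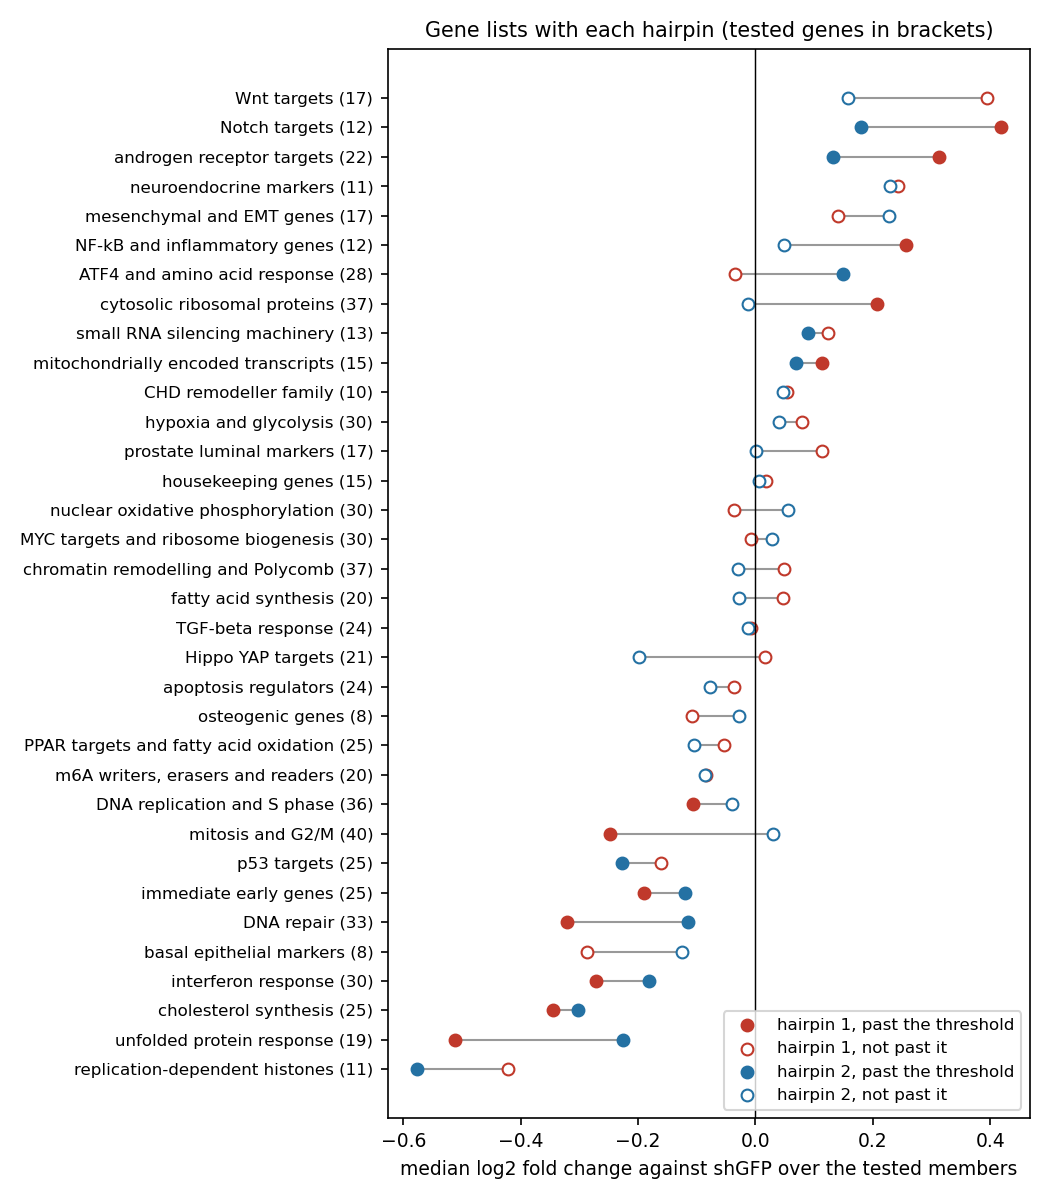
Median log2 fold change against shGFP (horizontal axis) over the tested members of each of the 34 gene lists (vertical axis, number of tested members in brackets), with hairpin 1 in red and hairpin 2 in blue. Filled points passed the camera test with that hairpin and open points did not; the medians of the unfolded protein response list were -0.51 and -0.23.

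The other 19 lists did not pass on the mean of both hairpins, although members of each changed. Prostate luminal markers had 8 of 17 higher, 4 lower and 5 not passed (camera, adjusted p = 0.18), where the homeobox gene HOXB13 rose by 0.64 on the log2 scale and the surface glycoprotein gene CD24 and the pioneer factor gene FOXA1 fell by 1.20 and 0.29. Basal markers had 1 of 8 higher, 3 lower and 4 not passed (1 and 4 adjusted over the list alone, camera adjusted p = 0.65). The integrin gene ITGA6 rose by 1.86, and CAV1 and the laminin chain gene LAMB3 fell by 0.89 and 0.81. Neuroendocrine markers had 6 of 11 higher, 1 lower and 4 not passed (camera, adjusted p = 0.12), with SYP, synaptophysin, and the splicing factor gene SRRM4 higher by 0.68 and 0.79, ONECUT2 higher by 0.27, and CHGB, under 1 CPM in each group, lower (-1.72). Mesenchymal genes had 7 of 17 higher, 3 lower and 7 not passed (8 and 4 adjusted over the list alone, camera adjusted p = 0.075), with COL6A1, CDH2 and MMP14 higher by 0.43, 0.28 and 0.52 and FN1, fibronectin, by 0.26 (-0.01 with hairpin 1 and 0.53 with hairpin 2). The m6A list had 3 of 20 higher, 11 lower and 6 not passed (camera, adjusted p = 0.088). The methyltransferase cofactor gene RBM15B and the reader gene IGF2BP2 rose by 0.60 and 0.41, IGF2BP3, METTL14 and YTHDF3 fell by 0.42, 0.37 and 0.24, and METTL3 had a log2 fold change of 0.03 that did not pass. In these lists the counts adjusted over the list alone were the same wherever none are given.

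Apoptosis regulators had 3 of 24 higher, 10 lower and 11 not passed (4 and 10 adjusted over the list alone, camera adjusted p = 0.37), with BAK1 higher by 0.46 and the inhibitors BIRC2 and MCL1 lower by 0.36 and 0.15 on the log2 scale. MYC targets had 10 of 30 higher, 6 lower and 14 not passed (camera, adjusted p = 0.37), with CAD and HSPE1 higher by 0.20 and 0.32, and NOP58 lower (-0.18), a call lost with the GC content and length correction. Nuclear oxidative phosphorylation genes had 7 of 30 higher, 5 lower and 18 not passed (camera, adjusted p = 0.87), with UQCRFS1 and ATP5F1B higher by 0.17 and 0.10, and NDUFA4 (-0.15) and UQCRB (-0.16) lower, calls that the same correction ended. NF-kB genes had 5 of 12 higher, 2 lower and 5 not passed (camera, adjusted p = 0.063), among them TNFAIP2 (0.87), the cytokine gene CSF1 (0.70), SOD2 (0.23) and NFKB2 (0.18, lost with that correction). The NF-kB list passed with a filter of at least 1 CPM in 6 libraries (camera, adjusted p = 0.024) and without shGFP replicate 2 (camera, adjusted p = 0.039). Hypoxia and glycolysis genes had 11 of 30 higher, 5 lower and 14 not passed (camera, adjusted p = 0.12), with ENO1 higher by 0.14 and ANGPTL4 and EGLN3 lower by 0.31 and 0.70. The fatty acid synthesis list had 7 of 20 higher, 7 lower and 6 not passed (camera, adjusted p = 0.65), with ACSL1 higher by 0.69 and ACSL3, FADS1 and the desaturase gene SCD lower by 0.61, 0.41 and 0.19. PPAR targets had 5 of 25 higher, 10 lower and 10 not passed (camera, adjusted p = 0.37), with PDK4 and CPT1A higher by 0.48 and 0.25, and ACAA2 lower by 0.68. Counts adjusted over the list alone were the same in the 6 lists for which none are given.

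Osteogenic genes had 1 of 8 higher, 4 lower and 3 not passed (3 and 4 adjusted over the list alone, camera adjusted p = 0.29). TNFRSF11B, osteoprotegerin, and BMP2 fell by 2.42 and 0.94 on the log2 scale, COL1A1 rose by 0.52, and ALPL fell by 0.32, a call lost without shGFP replicate 2 (-0.26). TGF-beta response genes had 7 of 24 higher, 8 lower and 9 not passed (camera, adjusted p = 0.61), with TGFB1 and LTBP3 higher by 0.64 and 0.42 and ID1 and ID2 lower by 0.45 and 0.66. YAP targets had 6 of 21 higher, 7 lower and 8 not passed (camera, adjusted p = 0.62), with WWC1 higher by 0.26 and NT5E, CCN1 and IGFBP3 lower by 1.17, 0.96 and 0.17. Wnt targets had 7 of 17 higher, 3 lower and 7 not passed (camera, adjusted p = 0.45), with CD44 higher by 0.47 and the Wnt inhibitor gene DKK1 and CCND1, cyclin D1, lower by 1.41 and 0.41. The median of the Wnt list was 0.31, while fry, which weighs each gene by its own spread, gave the direction lower (adjusted p = 3.3e-05). Chromatin remodelling and Polycomb genes had 10 of 37 higher, 9 lower and 18 not passed (camera, adjusted p = 0.87), with CBX2 and CBX8 higher by 0.45 and 0.25 and SMARCA5 and SUZ12 lower by 0.29 and 0.36. Housekeeping genes had 7 of 15 higher, 3 lower and 5 not passed (camera, adjusted p = 0.37), with EEF1A1 and RPLP0 higher by 0.16 and 0.13 and HPRT1 lower by 0.61. The median and the mean of the chromatin and housekeeping lists differed in sign, and the counts adjusted over the list alone were the same in the lists of these paragraphs where none are given. Immune and endothelial markers had 2 tested genes each, too few for a list test, and their highest mean levels were 0.616 CPM and 11.8 CPM. CD14 (0.03), ESAM (0.36) and EGFL7 (0.10) did not pass, although ESAM passed without shGFP replicate 1 (0.53), replicate 3 of hairpin 1 or replicate 1 of hairpin 2 (0.42 each).

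**Figure D3:**
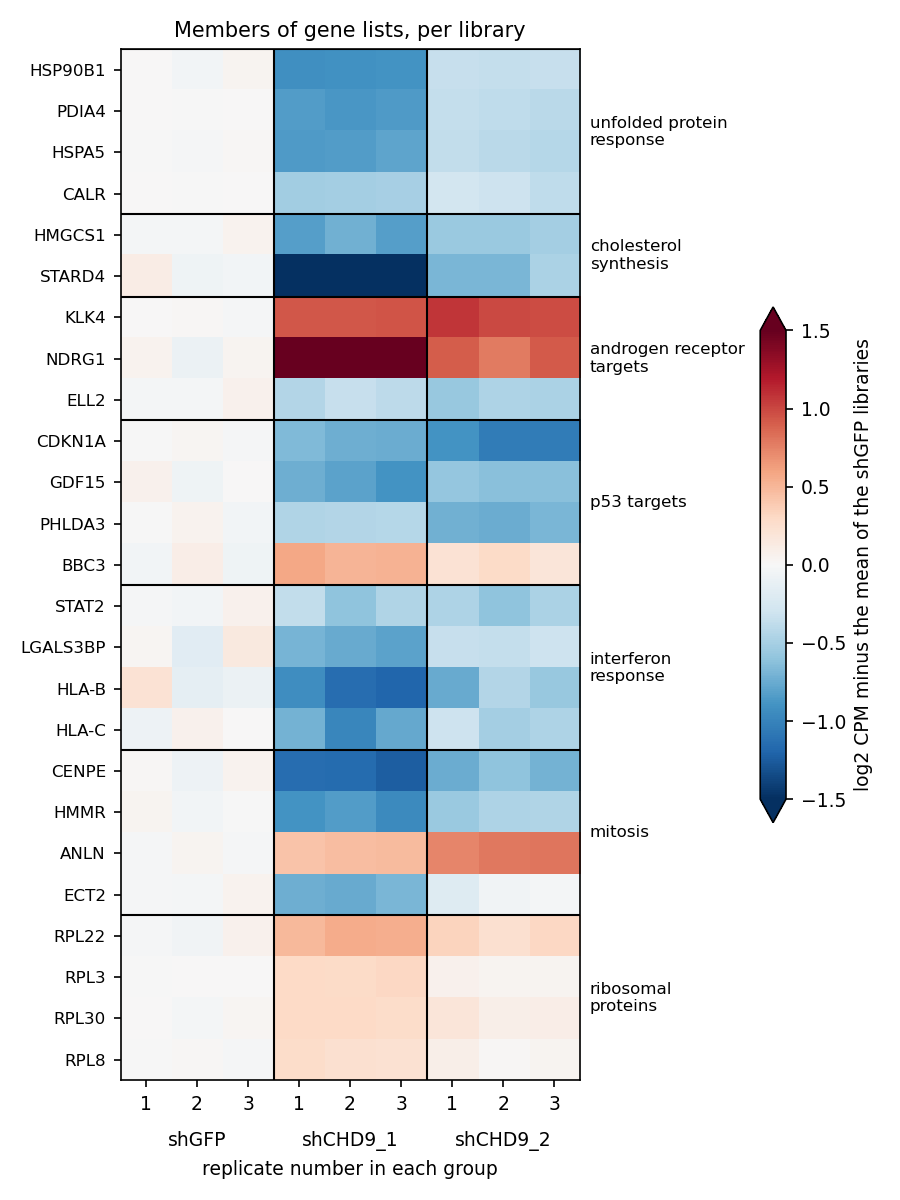
Log2 CPM minus the mean of the 3 shGFP libraries (colour, saturating beyond 1.5 in either direction) for members of 7 lists (vertical axis) in each of the 9 libraries (horizontal axis, replicates 1 to 3 of shGFP, shCHD9_1 and shCHD9_2). HSP90B1, for example, fell by 0.63 on average over the hairpins, and KLK4 rose by 0.98.

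Each hairpin was then compared with shGFP on its own, since a hairpin can also act on RNAs other than its target. With both hairpins, endoplasmic reticulum chaperones and cholesterol synthesis genes fell. With hairpin 1, 17 unfolded protein response genes were lower and 2 not passed (camera, adjusted p = 1.8e-17), and with hairpin 2 the same numbers were lower and not passed (camera, adjusted p = 1.5e-13), with medians of -0.51 and -0.23. Cholesterol synthesis genes had 20 of 25 lower, none higher and 5 not passed with hairpin 1 and 19 lower, 1 higher and 5 not passed with hairpin 2 (20 and 1 adjusted over the list alone), with camera adjusted p of 1.3e-10 and 8.0e-11. Androgen receptor targets had 14 higher, 2 lower and 6 not passed with hairpin 1 (14 and 3 adjusted over the list alone), and 11 higher, 4 lower and 7 not passed with hairpin 2. Their camera adjusted p was 2.0e-05 and 0.0040, the second being lost with an estimated correlation (adjusted p = 0.062).

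With hairpin 1, 7972 genes changed, 4023 higher and 3949 lower, and with hairpin 2, 6009 genes, 2891 higher and 3118 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). More than 2-fold changes numbered 691 and 385. In all, 4522 genes changed in the same direction with both hairpins, 2225 higher and 2297 lower, which is 56.7% of the hairpin 1 calls and 75.3% of the hairpin 2 calls. Independent lists of these sizes would share 690 higher and 731 lower genes. Simulated unchanged hairpin groups against the same controls shared none in 20 simulations. Those simulations held no changed gene, so hardly any calls could arise. Their shared count therefore gives no expectation for the 4522. Across genes, which are not independent replicates, the correlation of the fold changes was 0.78, against 0.52 in the simulations, and the covariance was 0.140, against 0.0167. The shared sign was found in 77.3% of genes, against 67.3% in the simulations. The 3 shGFP libraries cannot be split into 2 sets of 2, so part of the excess of shared calls may come from the shared controls. The covariance exceeded the simulated value by 0.123. That value holds the spread between the shared control libraries, and no shift common to all 3 of them. Of the 4522 genes, 759 changed by more than 1.5-fold with each hairpin, and 3241 had the smaller fold change with hairpin 2, 1433 of them past the test of the difference, while 217 passed it with the larger change with hairpin 2. AGR2, for example, fell by 3.48 with hairpin 1 and by 2.43 with hairpin 2 on the log2 scale, whereas VCAN changed by -1.77 and -1.84, FLRT3 by -1.80 with either, and OAF by 1.52 and 1.60. A call on the mean can also come from a single hairpin. Among the list members named above that differed between the hairpins, HPRT1, EEF1A1, RPLP0, RPL8, SYP, ISG15, NFKB2, DDIT3, PSAT1 and AARS1 passed with hairpin 1 and not with hairpin 2. FN1, FDPS, IGFBP3, XRCC2, MCM4, PLK1, AURKA, TMEM79, STEAP4 and MT-CO1 passed with hairpin 2 and not with hairpin 1, and TP53INP1 and KIF11 were called in opposite directions.

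**Figure D4:**
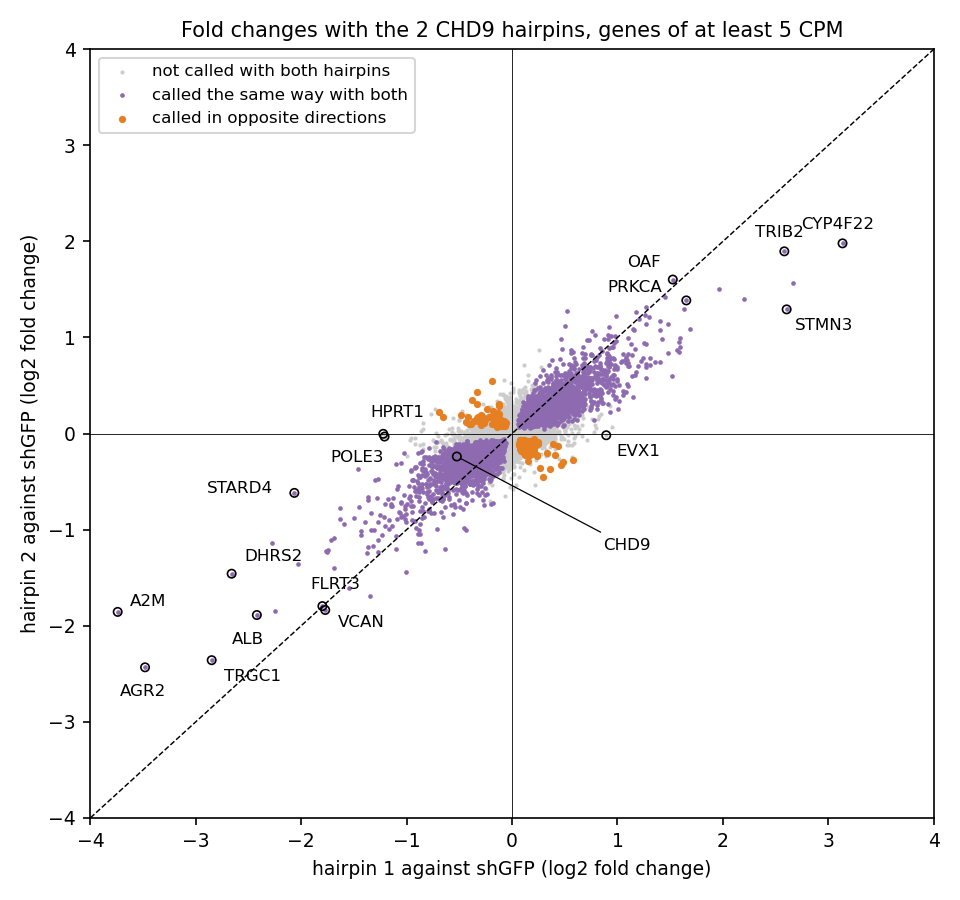
Log2 fold change with hairpin 1 (horizontal axis) and with hairpin 2 (vertical axis) against shGFP for the 11176 genes of at least 5 CPM, coloured by whether they were called the same way with both hairpins, in opposite directions, or not with both; the dashed line marks equal change. AGR2 lay at -3.48 and -2.43, and HPRT1 at -1.22 and -0.00.

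Some lists passed with a single hairpin. Hairpin 1 alone gave a call for mitosis genes, 29 of 40 lower, 2 higher and 9 not passed (29 and 3 adjusted over the list alone, camera adjusted p = 1.2e-09, and adjusted p = 0.020 with an estimated correlation). With hairpin 2, 9 were lower, 10 higher and 21 not passed, the same adjusted over the list alone (camera, adjusted p = 0.40). Ribosomal protein genes rose with hairpin 1, 35 of 37 higher and 2 not passed (camera, adjusted p = 1.0e-21, and adjusted p = 0.18 with an estimated correlation), while hairpin 2 gave 3 higher, 9 lower and 25 not passed (camera, adjusted p = 0.25). Replication genes had 22 of 36 lower and 14 not passed with hairpin 1 (camera, adjusted p = 7.2e-07), and 13 lower, 5 higher and 18 not passed with hairpin 2 (14 and 6 adjusted over the list alone, camera adjusted p = 0.054). NF-kB genes passed narrowly with hairpin 1, with 5 of 12 higher and 2 lower (camera, adjusted p = 0.047, and adjusted p = 0.18 with an estimated correlation). Hairpin 2 alone gave calls for p53 targets, 18 of 25 lower, 1 higher and 6 not passed (camera, adjusted p = 2.6e-07), where hairpin 1 gave 13 lower, 3 higher and 9 not passed (camera, adjusted p = 0.054). It also gave calls for ATF4 genes, 18 of 28 higher, 2 lower and 8 not passed (18 and 3 adjusted over the list alone, camera adjusted p = 5.9e-07, and adjusted p = 0.045 with an estimated correlation), where hairpin 1 gave 11 higher and 8 lower (camera, adjusted p = 0.76). Histone genes and small RNA silencing genes passed with hairpin 2 (camera, adjusted p = 0.0049 for each, and adjusted p = 0.073 and 0.24 with an estimated correlation), where hairpin 1 gave camera adjusted p of 0.087 and 0.12. The difference between the hairpins did not pass for either list (camera, adjusted p = 0.63 for each) or for NF-kB genes (camera, adjusted p = 0.087). DNA repair, interferon, Notch, immediate early and mitochondrially encoded lists passed with each hairpin in the direction given for their mean. With an estimated correlation, the immediate early and mitochondrial calls were lost with hairpin 1 (camera, adjusted p = 0.16 and 0.28), and with hairpin 2 all 5 of these calls were lost (camera, adjusted p = 0.072 for interferon to 0.42 for mitochondrial transcripts).

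The difference between the hairpins was tested directly, as hairpin 1 against hairpin 2. Mitosis, DNA repair and replication genes and endoplasmic reticulum chaperones were lower with hairpin 1 than with hairpin 2. Ribosomal protein genes were higher, a call lost with an estimated correlation (camera, adjusted p = 0.052). Log2 differences between the hairpins followed GC content (Spearman 0.30 across genes, which are not independent replicates). The list tests between the hairpins, and those with each hairpin alone, were not rerun with the GC content and length correction. HPRT1 (ENSG00000165704.15, chromosome X, 134460153 to 134520513), the purine salvage enzyme gene often used as a reference, was at 81.9 ± 2.52 CPM in shGFP, 35.1 ± 2.24 with hairpin 1 and 81.7 ± 2.73 with hairpin 2 (SD, n = 3 each). POLE3 (ENSG00000148229.13, chromosome 9, 113407235 to 113410672), a DNA polymerase epsilon subunit gene, was at 134 ± 7.95, 57.7 ± 1.57 and 131 ± 1.65 CPM (SD, n = 3 each). HPRT1 and POLE3 carry CTTCTAA in their annotated 3' UTR.

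In this comparison 4921 genes differed, 2623 higher and 2298 lower with hairpin 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 122 differed by more than 2-fold. Among genes of at least 5 CPM, the most reduced with hairpin 1 relative to hairpin 2 were A2M (log2 difference -1.88, SE 0.20), STARD4 (-1.45, SE 0.13), HPRT1 (-1.22, SE 0.04), DHRS2 (-1.20, SE 0.05) and POLE3 (-1.18, SE 0.04). At that level the most raised were STMN3 (1.31, SE 0.05), CYP4F22 (1.16, SE 0.09), CYP1A2, at 20.5 CPM with hairpin 1 and 9.57 CPM with hairpin 2, AK5, an adenylate kinase gene (0.91, SE 0.08), and the homeobox gene EVX1 (0.91, SE 0.10). The largest edgeR Benjamini-Hochberg adjusted p among these 10 was 6.0e-10, for A2M. EVX1 rose with hairpin 1 (0.89) and had a log2 fold change of -0.02 with hairpin 2, while AK5 rose with both (1.52 and 0.60).

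Of the 34 lists, 15 differed between the hairpins, 8 higher and 7 lower with hairpin 1 (camera), and 7 of them with an estimated correlation as well. All 37 ribosomal protein genes were higher with hairpin 1, the same adjusted over the list alone (camera, adjusted p = 7.1e-47, and adjusted p = 0.052 with an estimated correlation), among them RPLP0 (0.27 against -0.01) and RPL3 (0.30 against 0.05). Mitosis genes had 35 of 40 lower, none higher and 5 not passed (36 lower adjusted over the list alone, camera adjusted p = 2.0e-26, and adjusted p = 0.0059 with an estimated correlation). ECT2 fell by 0.73 with hairpin 1 and by 0.09 with hairpin 2. Unfolded protein response genes had 13 of 19 lower and 6 not passed (camera, adjusted p = 5.7e-15), DNA repair genes 22 of 33 lower and 11 not passed (25 adjusted over the list alone, camera adjusted p = 3.7e-10), and replication genes 24 of 36 lower and 12 not passed (26 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.4e-08). ATF4 genes had 16 of 28 lower, 4 higher and 8 not passed (19 and 4 adjusted over the list alone, camera adjusted p = 1.5e-06), and cholesterol synthesis genes 10 of 25 lower, 1 higher and 14 not passed (camera, adjusted p = 0.0010). Androgen receptor targets had 12 of 22 higher, 2 lower and 8 not passed (14 and 2 adjusted over the list alone, camera adjusted p = 0.00062). These 7 lists, mitosis included and ribosomal proteins not, are those that held with an estimated correlation.

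The other 7 calls between the hairpins were lost with an estimated correlation. Oxidative phosphorylation genes had 12 of 30 lower and 1 higher (camera, adjusted p = 0.00022, and adjusted p = 0.24 with an estimated correlation). Mitochondrially encoded transcripts had 8 of 15 higher and 1 lower (camera, adjusted p = 0.0013, and adjusted p = 0.35 with an estimated correlation), and Notch genes 6 of 12 higher and none lower (camera, adjusted p = 0.0038, and adjusted p = 0.067 with an estimated correlation). Targets of p53 had 11 of 25 higher and 2 lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.0041, and adjusted p = 0.052 with an estimated correlation), with CDKN1A at 189 CPM with hairpin 1 and 155 CPM with hairpin 2. Chromatin genes had 17 of 37 higher and 2 lower (19 and 5 adjusted over the list alone, camera adjusted p = 0.0052, and adjusted p = 0.067 with an estimated correlation), and luminal markers 10 of 17 higher and 3 lower (camera, adjusted p = 0.0090, and adjusted p = 0.099 with an estimated correlation). YAP targets had 8 of 21 higher and 3 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation). Where no counts adjusted over the list alone are given for this comparison, they were the same.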

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

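The GC content and length correction, the seed test on protein-coding genes alone, the interval on the matched genes and the choice of example genes with opposite changes came after the results were seen. The hairpins were compared directly, and they differed in several ways. The fall of CHD9 itself was larger with hairpin 1 by -0.28 on the log2 scale. In all, 4921 genes differed between the hairpins, or 29.2% of those tested, as did 107 of the 163 named genes, some of which were chosen for such a difference. Of the 34 gene lists 15 differed, 7 of them with an estimated correlation as well. Among the genes that differed, 145 were called in opposite directions, 87 higher with hairpin 1 and lower with hairpin 2, and 58 the reverse. Examples of at least 5 CPM are LBR, a lamin receptor gene (-0.69 with hairpin 1, 0.23 with hairpin 2), the p53 target TP53INP1 (0.58, -0.28), the antiproliferative gene BTG2 (0.46, -0.33), the cystine transporter gene SLC7A11 (-0.19, 0.55) and the kinesin KIF14 (-0.33, 0.30). Between the hairpins, 1 of the 10 splits of the 6 libraries gave as many genes, the real one, with 4935 genes in a fit on those libraries against 2 in the highest other split. The splits are too few for a share under 0.05.

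The first pattern is the 4522 genes that changed in the same direction with both hairpins, such as AGR2, ALB and TRIB2. Log2 fold changes in the mean contrast followed GC content (Spearman 0.32 across genes, which are not independent replicates), and after the correction they no longer did (-0.03). With the correction, 3268 of the genes, or 72.3%, were still called in the same direction with both. This argues against GC content and exonic length as the whole cause, while the other calls may depend on them. Gains or losses of chromosome segments are also argued against for most of the genes, since 2.01% of them (91 genes) lay in the 4 of 156 bins of 20 Mb whose median log2 fold change was beyond 0.2. Whether effects scaled with the CHD9 level cannot be told apart from other shapes, because the slope of hairpin 2 on hairpin 1 effects was 0.672 (95% interval over genes 0.655 to 0.689) and 0.616 for genes of at least 5 CPM, and the ratio of the CHD9 changes, 0.456, had a 95% interval of 0.217 to 0.697.

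Loss of CHD9 stays open as a biological explanation of the shared changes. A response to either CHD9 hairpin that differs from that to the GFP hairpin and a difference between the cultures of the groups stay open too, since each group has its own hairpin. In the mean contrast, 1 of 100 regroupings of the libraries, the real one, gave 7675 genes and the highest other 5216. For the shared genes, 1 of 100, the real one, gave 4522 genes and the highest other 3130. For gene lists, 3 of 100 regroupings gave as many as the real 15, and the highest other gave 15. These shares lie under the 0.05 set beforehand and argue against arbitrary labels. Other regroupings mix libraries of groups that differ, which widens the spread within their groups. They called a median of 0 genes in the mean contrast. The shares thus show that libraries differ by group, and not why. The other regroupings passed a median of 7 lists, so a single list call is weaker evidence than the number of lists. For hairpin 1 against shGFP, 1 of 10 splits, the real one, gave 8048 genes and the highest other 0, and for hairpin 2, 1 of 10, the real one, gave 5820 and the highest other 0, in fits on 6 libraries. Those splits are too few for a share under 0.05.

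The second pattern is 111 genes more than 1.5-fold lower with hairpin 1 than with hairpin 2 that fell with hairpin 1 and were not called lower with hairpin 2, such as HPRT1 and POLE3. A hairpin can act like a microRNA through its seed, on 3' UTRs that match it, and a search over all of these genes was void because 59.5% could be searched, 44 of the genes not being protein-coding. Of the 67 protein-coding genes 66 could be searched, and 35 of them carried the word CTTCTAA, 3.26 times as often as other genes of the same UTR length. The word had the lowest z of the scan (-10.8, against -3.70 for the next word that does not overlap it and -4.78 as the lowest of 100 permutations). The word was picked by the same difference, so the 3.26 shows how far it covers these genes and is no evidence beyond the z. Picked in that way, the word was also in 598 of 2065 searched genes lower with hairpin 1 than with hairpin 2. This was 1.86 times the share for their UTR length, against 0.516 times for genes higher with hairpin 1. Of genes lower with hairpin 1 than in shGFP, 22.1% carried it, against 13.8% for their UTR length. For genes lower with hairpin 2 than in shGFP, it was 16.9% against 15.2%. A seed effect of hairpin 1 is therefore a candidate explanation for part of the protein-coding genes of this pattern. It is also a candidate for part of the other genes lower with hairpin 1. The hairpin sequence, which would settle whether the word matches, is not given in the sources used here.

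For the same 111 genes, GC content and exonic length are argued against as the whole cause. After the correction, 102 of these genes (91.9%) were still lower with hairpin 1. Of genes lower with both hairpins, 18.9% carried CTTCTAA, against 15.2% of other genes of the same UTR length. HPRT1, POLE3 and STARD4 carry it, and A2M and DHRS2 do not. Without the carriers of CTTCTAA or of the overlapping TTCTAAA, 26 of 31 mitosis genes and 21 of 29 replication genes were still lower with hairpin 1, so carriers alone do not account for these lists. The stronger fall of CHD9 with hairpin 1 stays open as a biological explanation and was not tested for these genes.

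The third pattern is that all 37 ribosomal protein genes were higher with hairpin 1 than with hairpin 2, such as RPLP0 and RPL3, with a median log2 difference of 0.21. If abundant transcripts had shifted together, other genes matched on exonic length, GC content and mean CPM would need at least 50% of that difference. Exonic length joins all annotated exons of a gene, with medians of 3717 bases for ribosomal protein genes and 3625 for matched genes. It is not the length of the transcripts present, so the test cannot decide about a shift of short transcripts. The 98 matched genes, each counted as often as it was matched, had a median of 0.05, or 22.3% (95% interval 11.5 to 36.2). The interval resamples genes as independent. Ribosomal protein genes vary together (estimated correlation 0.66 in the mean contrast), so the interval may be too narrow. The share of 22.3% lies below 50% and argues against a shift of abundant transcripts as the whole cause, though this interval cannot tell how firmly. The interval crosses the 25% set beforehand as the bound against it, so a part may come from it. Scaling is argued against, since the lowest median under 3 other scalings was 0.17. A different growth or translation state of the hairpin 1 cells stays open, untested, as does a difference between cultures, and the list call was lost with an estimated correlation.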

How the results depend on the processing

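The GC content and length correction was chosen after the data were seen. Under the size factors of DESeq2, the DESeq2 Wald test, voom, both other low-count filters, an adjusted p under 0.01, fits on fewer groups and the correction, the counts of changed genes stayed within 1.5 times those reported. For the mean contrast they ranged from 5272, with the 6 CHD9 libraries as a single group, to 7669, with the replicate number as a replicate block. A minimum fold change of 1.5 in glmTreat left 396 genes, 179 higher and 217 lower, as that test by construction asks for larger changes. The replicate numbers do not pair the libraries, as the deviations of libraries with the same number correlated by -0.022 to 0.040 over 9 pairs. With the replicate block there were 7965 genes for hairpin 1, 5994 for hairpin 2, 4932 between the hairpins, 4490 shared genes and 15 lists. Leaving out 1 library at a time gave 6625 to 7573 genes for the mean contrast, 7128 to 8106 for hairpin 1, 5133 to 5977 for hairpin 2, 3940 to 4944 between the hairpins and 3814 to 4294 shared genes. Of the 4522 shared genes, the alternatives kept from 72.3% (the correction) to 99.5% (DESeq2 size factors), and without shGFP replicate 3 80.8%.

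CHD9 stayed lower under every alternative run for it, with log2 fold changes for hairpin 1 of -0.58 to -0.49 when 1 library was left out and -0.39 with the correction. For hairpin 2 they were -0.29 to -0.20 when 1 library was left out, and the call was lost without shGFP replicate 3 (-0.20, adjusted p = 0.054, against 0.0028 to 0.027 under the other alternatives). The cause was not tested. CHD3 reversed with the correction (-0.027), and the cause was not tested. Of the other named genes' values under the alternatives, 2083 kept direction and call, 16 lost the call and 6 gained one, and the 130 values for the hairpin differences all kept theirs.

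With an estimated correlation, which allows for genes of a list varying together, 7 lists passed in place of 15. The histone list lost its call although its estimated correlation was -0.052, below the preset 0.01. Lists that kept their calls also weakened at correlations below the preset. Androgen receptor targets (-0.018) went from a camera adjusted p of 0.00021 to 0.042, and p53 targets (-0.014) from 0.00056 to 0.042. Genes varying together thus do not account for every loss, and a loss under this setting does not by itself show that they do. The cause was not tested. The directional test fry gave 30 lists, because by construction it does not compare a list with other genes. It gave the direction lower for the Wnt list, whose median is 0.31. With hairpin 2 alone the median of mitosis genes was 0.0305 and that of ribosomal proteins -0.0135. With hairpin 1 alone that of ATF4 genes was -0.0345. Each lay against the direction of the mean contrast, and none of these lists passed with that hairpin (camera, adjusted p = 0.40, 0.25 and 0.76). These lists differed between the hairpins in the direct test, ribosomal proteins only with the preset correlation. In all, 544 list values kept direction and call, 13 lost the call and 17 gained one. The correction ended the mitosis call in the mean contrast, the only contrast whose lists were rerun with it, as the median moved from -0.12 to -0.05. The cause was not tested for the lists in which it ended a call. At these depths the simulated test recovered 62.7% of genes with the smallest simulated change in the mean contrast. The simulation changed far fewer genes than were called in these libraries, which makes the adjusted p harder to pass. Its share therefore cannot tell how often small changes were missed here. Alternatives for values other than counts were not run, since the values are counts.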

Other observations

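All tests in this part were chosen after the results were seen. A seed effect of the GFP hairpin would lower its targets in shGFP and make them look higher with both CHD9 hairpins. The word most depleted in this way, CAGTACA, had a z of -6.12 against -4.98 for the lowest of 100 permutations. Of the 2010 searched genes higher with both hairpins, 271 carried it (13.5%), against 10.7% of other genes of the same UTR length, a ratio of 1.26. Such an effect may touch some genes, and the ratio argues against it as the cause of most of the rises.

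Families of genes were also grouped by symbol stem, 165 stems with at least 10 genes each. In the mean contrast, RAD genes had 10 of 18 lower and none higher (camera, adjusted p = 0.013), RPL genes had 31 of 47 higher and 3 lower (camera, adjusted p = 3.3e-07) and RPS genes had 25 of 38 higher and 4 lower (camera, adjusted p = 0.0019). Between the hairpins, KIF genes had 16 of 33 lower with hairpin 1 and 3 higher (camera, adjusted p = 0.0017), NUP genes 11 of 22 lower and none higher (camera, adjusted p = 0.00064) and MCM genes 7 of 10 lower and none higher (camera, adjusted p = 0.012). KDM genes had 8 of 18 higher with hairpin 1 and 1 lower (camera, adjusted p = 0.023). RPL, RPS, MAPK and EEF genes also passed as higher with hairpin 1, and HSPA, RAD, CEP and DHX genes as lower (camera, adjusted p = 1.3e-35 for RPL to 0.044 for DHX). None of these stems passed with an estimated correlation (camera, adjusted p = 0.42 or more).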
